A study of Mus musculus with 9 samples.

How the data were processed

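Total RNA of mouse liver was sequenced in 9 libraries, 3 from mice given vehicle, 3 given AdipoRon and 3 given AdipoRonPEG5, all from C57BL/6 mice per the labels. The labels give 5 mg/kg, injected 2 times a day for 5 days, for the compounds and for the PBS vehicle alike. No dose of an active compound applies to PBS, so that the dose of each compound is not certain. The deposited table holds raw read counts per gene, 1 column per library, and beside them FPKM computed by the authors. Each deposited FPKM equals the count divided by a whole-number gene length and the library's total: the implied length was whole within 0.01 for 99.995% of nonzero values. The FPKM served only to recover these lengths, and the counts were used for every comparison. The submitters list STAR 2.5, TopHat, HTSeq 0.6.1, DESeq2 and edgeR with no role or order; the genome build, annotation, strand setting and read filters were not given in the sources used here. The columns of the AdipoRonPEG5 libraries carry another prefix than that name in the table and were tied to samples through the sample descriptions.

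The table has 35275 entries, of which 21500 have a count in at least 1 library. A total of 126 entries share their name with another entry and 27 have names turned into dates, so that they cannot be matched to genes. Gene identity was taken from the symbols in the table. Of 720 symbols in the gene lists, 716 were found, 4 of them through an older symbol: Col4a3bp for Cert1, Gm6484 for Angptl8, Emr1 for Adgre1 and Ctgf for Ccn2. GC content, used in 1 alternative only, came from GENCODE mouse release M21 and was found for 98.7% of tested genes.

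Tests were run in R 4.3.3 with edgeR 4.0.16. All 9 libraries entered 1 quasi-likelihood fit with 3 group means (TMM normalization, filterByExpr, robust set to FALSE, no replicate block), which kept 13151 genes. Genes passed at a Benjamini-Hochberg adjusted p of 0.05 over all genes tested, in each of 3 comparisons: AdipoRonPEG5 against vehicle, AdipoRon against vehicle, and AdipoRonPEG5 against AdipoRon. Gene lists (42 fixed, 38 with at least 3 tested members) were tested with camera of limma 3.58.1 at a preset correlation of 0.01 on log-CPM with a prior count of 2, with Benjamini-Hochberg adjustment over the 38 lists, and again with the correlation estimated for each list. The lists of neutrophils, exocrine pancreas and skeletal muscle (1 tested member each) and of gut epithelium (2) were too small to test. Fold changes are log2 values from the fit with standard errors; CPM are TMM-scaled, given as mean ± SD of 3 libraries. Intervals are at the 95% level, and intervals of count ratios cover counting error only.

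Named genes followed a rule: in each comparison, the 8 largest rises and the 8 largest falls among called genes with no overlap between the groups and a mean of at least 1 CPM, passing over unnamed gene models and pseudogenes; up to 3 called members of each of at most 8 called lists, by lowest p; up to 2 called members of any other list; and Adipor1 and Adipor2 whatever their test. Where 1 of these 8 lists had no called member, its 2 members with the lowest p were named; other called lists without a called member have none named. Other genes are said to have been chosen after their values were seen. The groups, tests, lists, naming rule and first set of alternatives were fixed before the data were examined. The alternatives were RLE size factors, total-count scaling, no filter, a filter at a mean of 1 CPM, DESeq2 1.42.0, limma-voom, only the 2 groups compared, a replicate block and each library left out in turn. Alternatives chosen after seeing the data were vehicle 1 thinned to 15860441 reads, a gene length trend or length and GC trends removed from each library, and vehicle 3 and AdipoRonPEG5 1 both left out. The fit was tested on simulated data with known changes and the same depths. For AdipoRonPEG5 against vehicle it recovered 32.8%, 82.1% and 93.9% of simulated changes of 1.5, 2 and 4-fold, with 2.80% false calls.

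Library totals ran from 13942322 to 18508950 counts, with 39473195 in vehicle 1. A floor of 3 counts lies between 0.076 and 0.215 CPM of the library total. The labels do not state that the libraries of a group come from separate animals. If they do not, the spread between them is technical, and the tests then say nothing of the variation between mice.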

Results

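Liver RNA from C57BL/6 mice was sequenced after 5 days of injections with vehicle, with AdipoRon, a small-molecule agonist of the adiponectin receptors, or with AdipoRonPEG5, a PEGylated analog of it. Each group held 3 libraries, and the labels give 5 mg/kg for both compounds in a sentence that gives it for the PBS vehicle too, so that the dose is not certain. The total count was 39473195 in vehicle 1 and between 13942322 and 18508950 in the other 8 libraries. The 10 most abundant genes took 15.5% to 17.6% of the counts, and mitochondrially encoded genes 3.85% to 5.29%. The first principal component of the log-CPM held 40.0% of the variance and set the groups in the order vehicle (-36.85 to -28.46), AdipoRon (-5.12 to 6.31) and AdipoRonPEG5 (29.84 to 34.50). Vehicle 3 and AdipoRonPEG5 1 stood apart from the rest of their groups in acute phase genes, which were chosen after their values were seen. Saa1, an acute phase protein of the liver, was at 4959 CPM in vehicle 3 and 1952 CPM in AdipoRonPEG5 1, against 45.1 to 497 CPM in the other 7 libraries.

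The mRNA of the adiponectin receptors, the targets of the parent compound, was measured well above the floor in all groups. Adipor2 was at 499.7 ± 32.8 CPM in vehicle, 495 ± 19.9 CPM in AdipoRon and 376 ± 13.1 CPM in AdipoRonPEG5 livers (SD, n = 3). It fell with AdipoRonPEG5 against vehicle (log2 fold change -0.41 ± 0.083 (SE), edgeR Benjamini-Hochberg adjusted p = 0.00767); with AdipoRon its log2 fold change was -0.013 ± 0.083 (adjusted p = 0.95). Between the compounds Adipor2 was lower with AdipoRonPEG5 (log2 difference -0.40, 95% confidence interval -0.58 to -0.21, edgeR Benjamini-Hochberg adjusted p = 0.0228), but the call ended without AdipoRon 1, AdipoRon 3, AdipoRonPEG5 1, AdipoRonPEG5 2 or AdipoRonPEG5 3 (adjusted p from 0.0622 to 0.10). Adipor1 was at 93.4 ± 4.57, 94.1 ± 8.03 and 104 ± 13.4 CPM. Its log2 fold changes of 0.15 ± 0.10 with AdipoRonPEG5 (adjusted p = 0.329) and 0.011 ± 0.10 with AdipoRon (adjusted p = 0.965) did not pass, nor did the difference between the compounds (0.14, 95% confidence interval -0.078 to 0.36). Of 6 tested receptor and adaptor genes, Adipor2 was the only one called in any comparison.

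**Figure D1:**
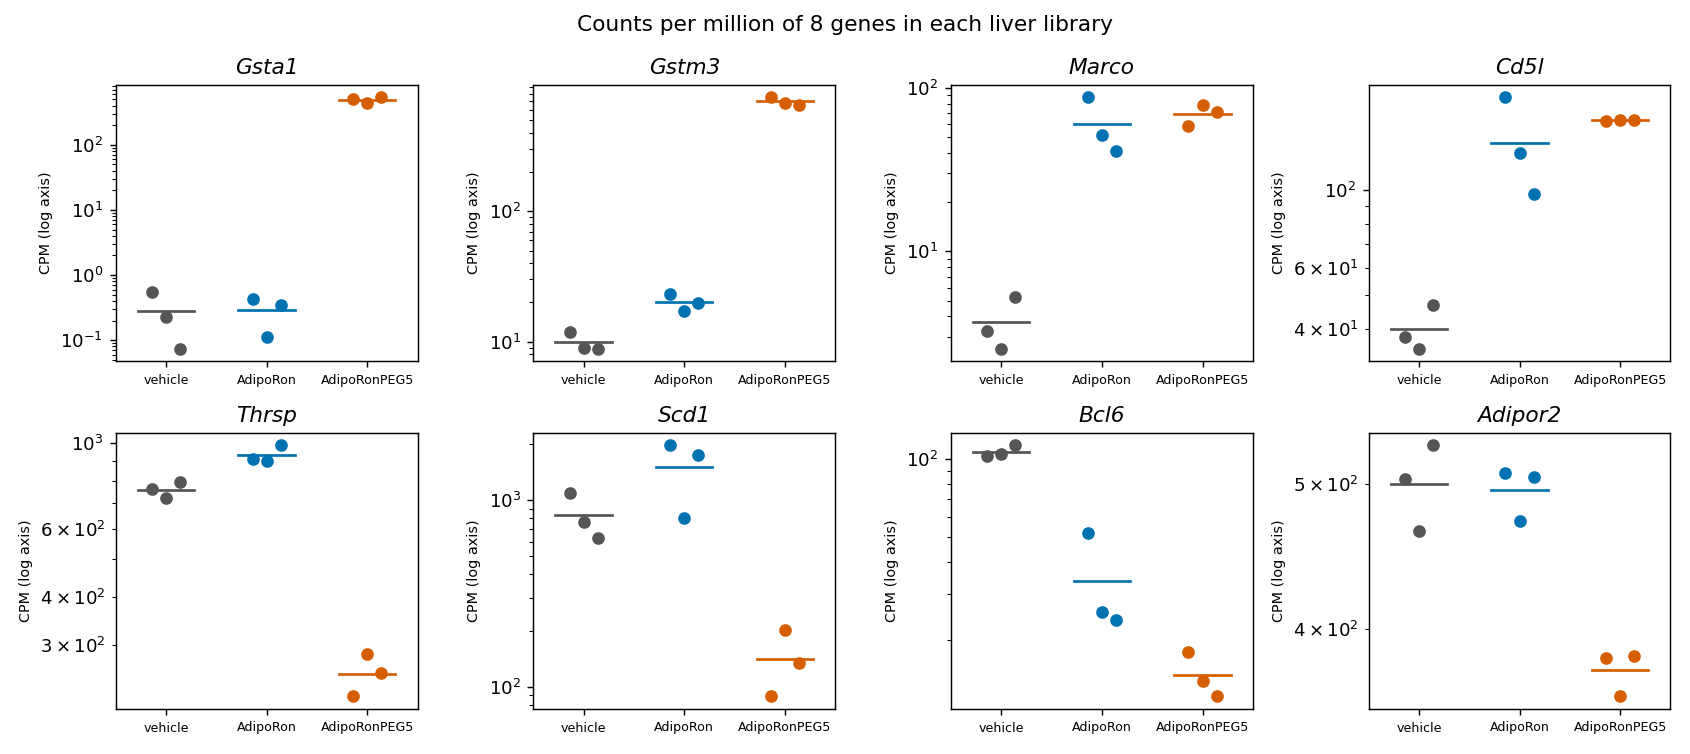
CPM (log axis) of 8 genes in each of the 9 libraries, 3 points per group with a line at the group mean. Gsta1 and Gstm3 were highest in AdipoRonPEG5 livers, Marco and Cd5l were above vehicle with both compounds, and Thrsp and Scd1 were lowest with AdipoRonPEG5.

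The first comparison asked what the PEGylated compound does in the liver. Of the genes named for the size of their rise with AdipoRonPEG5, the glutathione transferase gene Gsta1 came first, the cytochrome P450 gene Cyp2a4 next and the glutathione transferase gene Gstm3 after it. Glutathione transferases conjugate glutathione to reactive compounds. Gsta1 went from 0.279 ± 0.238 CPM in vehicle to 491 ± 49.0 CPM (SD, n = 3; log2 fold change 10.36 ± 0.29 (SE), edgeR Benjamini-Hochberg adjusted p = 7.77e-09), and to a log2 fold change of 11.61 without vehicle 1. Gstm3 went from 9.89 ± 1.76 to 696 ± 45.3 CPM (6.12 ± 0.16, adjusted p = 7.77e-09). Marco, a scavenger receptor of macrophages, rose from 3.7 ± 1.42 to 69.3 ± 10.5 CPM (4.26 ± 0.31, adjusted p = 3.64e-05). Scd1, a desaturase of fatty acid synthesis, fell from 830.0 ± 237 to 141 ± 56.1 CPM (-2.56 ± 0.37, adjusted p = 0.00153).

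Further large rises were those of Abcc12, an ABC transporter (log2 fold change 4.51 ± 0.38), Cd300e, a receptor of myeloid cells (4.09 ± 0.36), and the glutathione transferase Gstp2 (4.05 ± 0.38). Ubd, an interferon-inducible ubiquitin-like protein, was at 3.97 ± 0.58, and at 4.77 without vehicle 3. Cyp2a4 reached 15.8 ± 16.5 CPM (6.21 ± 0.91), with a log2 fold change of 4.91 without AdipoRonPEG5 2. The largest falls were in genes of major urinary proteins, the cytochrome P450 gene Cyp3a11 and the transcriptional repressor Bcl6. Cyp3a11, which oxidizes many drugs, went from 529.9 ± 338 to 40.6 ± 16.3 CPM (-3.70 ± 0.52, edgeR Benjamini-Hochberg adjusted p = 0.00126), and Bcl6 from 107 ± 5.57 to 14.6 ± 3.01 CPM (-2.87 ± 0.27). Mup9 was at -5.08 ± 1.04 (-4.12 without vehicle 3), and the call ended with limma-voom (adjusted p = 0.0963). Mup17 was at -3.83 ± 0.77 (-2.98 without vehicle 3, -4.52 without AdipoRonPEG5 2). Mup19 was at -3.23 ± 0.40 (-4.02 without AdipoRonPEG5 1) and Mup15 at -2.81 ± 0.82. The call of Mup15 ended without vehicle 2, vehicle 3, AdipoRonPEG5 1 or AdipoRonPEG5 3, or without vehicle 3 and AdipoRonPEG5 1 together (adjusted p from 0.0598 to 0.225); the value of Mup15 was -1.87 without vehicle 3 and -3.72 without AdipoRonPEG5 2. Ptgds (-3.08 ± 0.36) and Gpr98 (-2.66 ± 0.22) completed these 8 falls. Gsta1, Gsta2 and Gm10639, the Gstm genes and the Mup genes are close paralogs, and how reads that match several of them were counted is not given in the sources used here.

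The immune, stellate cell and cell cycle lists were called upward with AdipoRonPEG5 (values in parentheses are log2 fold changes ± SE). Of 18 macrophage and Kupffer cell genes, 16 rose, 0 fell and 2 did not pass (18 higher and 0 lower when adjusted over the list alone), with Marco, Cd5l (1.98 ± 0.19) and the complement gene C1qc (1.65 ± 0.18) among them. The macrophage list had a median log2 fold change of 1.84 (camera Benjamini-Hochberg adjusted p = 8.05e-14; adjusted p = 0.223 with an estimated correlation). Of 22 interferon response genes, 13 rose, 0 fell and 9 did not pass (14 higher and 0 lower when adjusted over the list alone). The rises include the chemokine Cxcl9 (2.20 ± 0.29) and the GTPase Gbp2 (1.74 ± 0.25). The interferon list had a median log2 fold change of 0.63 (camera adjusted p = 1.19e-05; adjusted p = 0.311 with an estimated correlation). Of 14 antigen presentation genes, 10 rose, 0 fell and 4 did not pass (11 higher and 0 lower when adjusted over the list alone). Called members include Ciita, the activator of MHC class II genes (2.61 ± 0.37), and H2-DMa (2.96 ± 0.47). The antigen presentation list had a median log2 fold change of 1.76 (camera adjusted p = 1.05e-06; adjusted p = 0.341 with an estimated correlation). Of 11 lymphocyte genes, 6 rose, 1 fell and 4 did not pass (9 higher and 1 lower when adjusted over the list alone). The chemokine Ccl5 was at 2.25 ± 0.33 and the B cell receptor gene Cd79b at 2.72 ± 0.44 (3.62 without vehicle 1). The lymphocyte list had a median log2 fold change of 2.25 (camera adjusted p = 7.04e-05; adjusted p = 0.219 with an estimated correlation), and the list's call ended with a filter at a mean of 1 CPM (adjusted p = 0.151). Of 16 stellate cell and matrix genes, 3 rose, 0 fell and 13 did not pass (8 higher and 1 lower when adjusted over the list alone). The growth factor gene Tgfb1, which many cell types express, was at 0.88 ± 0.14. The stellate list had a median log2 fold change of 0.54 (camera adjusted p = 0.00325; adjusted p = 0.311 with an estimated correlation). Of 16 cell cycle genes, 7 rose, 0 fell and 9 did not pass (7 higher and 1 lower when adjusted over the list alone). Top2a was at 2.07 ± 0.36 and Mcm6 at 1.62 ± 0.31. The cell cycle list had a median log2 fold change of 0.73 (camera adjusted p = 0.0145; adjusted p = 0.296 with an estimated correlation). Of 14 endothelial genes 1 rose and of 8 cholangiocyte genes 1, and neither list passed (adjusted p = 0.754 and 0.409).

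The NRF2 antioxidant list was called upward in the same livers as the macrophage list (median 1.84). Of 14 NRF2 genes, 9 rose, 0 fell and 5 did not pass (9 higher and 0 lower when adjusted over the list alone). The rises include Gsta1, the carbonyl reductase Cbr3 (3.89 ± 0.27) and the efflux transporter Abcc4 (3.04 ± 0.23). The NRF2 list had a median log2 fold change of 1.24 (camera Benjamini-Hochberg adjusted p = 3.02e-07; adjusted p = 0.219 with an estimated correlation). Of 21 drug metabolism genes, 5 rose, 2 fell and 14 did not pass (5 higher and 2 lower when adjusted over the list alone). Gstm3 and Gstm1 (3.52 ± 0.20), which conjugate rather than oxidize, led the rises, and the list did not pass (adjusted p = 0.0858). Of 24 sphingolipid genes, 6 rose, 0 fell and 18 did not pass (6 higher and 0 lower when adjusted over the list alone). Called members include the ceramidase Asah1 (0.68 ± 0.086) and the sphingosine kinase Sphk2 (0.40 ± 0.081). The sphingolipid list had a median log2 fold change of 0.22 (camera adjusted p = 0.0155; adjusted p = 0.243 with an estimated correlation), and the list's call ended without vehicle 3 and AdipoRonPEG5 1 together (adjusted p = 0.0768). Of 16 immediate early genes, 3 rose, 0 fell and 13 did not pass (4 higher and 0 lower when adjusted over the list alone). Myc was at 2.71 ± 0.51. The immediate early list had a median log2 fold change of 0.53 (camera adjusted p = 0.0187; adjusted p = 0.518 with an estimated correlation); the list's call ended without AdipoRonPEG5 3 (adjusted p = 0.0878). Of 20 ribosomal protein genes, 1 rose, 0 fell and 19 did not pass (0 higher and 0 lower when adjusted over the list alone). The ribosomal list had a median log2 fold change of 0.11 (camera adjusted p = 0.0423; adjusted p = 0.751 with an estimated correlation), and the list's call ended without vehicle 1, vehicle 2, AdipoRon 1, AdipoRon 3, AdipoRonPEG5 1 or AdipoRonPEG5 3, or with a replicate block (adjusted p from 0.0541 to 0.446). Of 17 ATF4 genes, 5 rose, 2 fell and 10 did not pass (6 higher and 2 lower when adjusted over the list alone). The serine synthesis gene Psat1 was at 3.39 ± 0.38 and Ddit3 at -1.24 ± 0.13; the list did not pass (adjusted p = 0.343).

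The lists of this paragraph were called downward with AdipoRonPEG5. Of 23 fatty acid and triglyceride synthesis genes, 0 rose, 10 fell and 13 did not pass (0 higher and 12 lower when adjusted over the list alone). Beside Scd1 (-2.56 ± 0.37), the lipogenic regulator Thrsp was at -1.59 ± 0.11 and the elongase Elovl6 at -1.72 ± 0.15. The lipogenesis list had a median log2 fold change of -0.54 (camera Benjamini-Hochberg adjusted p = 5.28e-05; adjusted p = 0.296 with an estimated correlation). In the same livers the adipose list had a median of -0.95, and the macrophage list one of 1.84. Cfd, an abundant adipose transcript, had 9 counts against 279 in vehicle, and its vehicle mean was 2.73 CPM, against 830.0 CPM for Scd1 and 759 CPM for Thrsp. Of 23 amino acid catabolism and urea cycle genes, 0 rose, 13 fell and 10 did not pass (0 higher and 16 lower when adjusted over the list alone). Called members include the urea cycle enzyme Otc (-0.55 ± 0.091) and the tyrosine breakdown enzyme Hpd (-0.65 ± 0.11). The amino acid list had a median log2 fold change of -0.34 (camera adjusted p = 1.83e-06; adjusted p = 0.223 with an estimated correlation). Of 17 gluconeogenesis genes, 0 rose, 9 fell and 8 did not pass (0 higher and 10 lower when adjusted over the list alone). Called members include the regulator Klf15 (-1.12 ± 0.12), the aminotransferase Tat (-1.92 ± 0.35) and the glucose-6-phosphate transporter Slc37a4 (-0.54 ± 0.097). The gluconeogenesis list had a median log2 fold change of -0.34 (camera adjusted p = 2.72e-05; adjusted p = 0.243 with an estimated correlation). Of 19 endoplasmic reticulum stress genes, 1 rose, 9 fell and 9 did not pass (1 higher and 11 lower when adjusted over the list alone). Herpud1 was at -1.40 ± 0.16 and Syvn1 at -1.49 ± 0.20, both of which act in the disposal of misfolded proteins. The ER stress list had a median log2 fold change of -0.49 (camera adjusted p = 9.06e-05; adjusted p = 0.478 with an estimated correlation). Of 17 periportal hepatocyte genes, 0 rose, 7 fell and 10 did not pass (0 higher and 8 lower when adjusted over the list alone). The gluconeogenic enzyme Pck1 was at -1.39 ± 0.28. The periportal list had a median log2 fold change of -0.33 (camera adjusted p = 0.000745; adjusted p = 0.243 with an estimated correlation). Of 17 bile acid genes, 0 rose, 5 fell and 12 did not pass (0 higher and 9 lower when adjusted over the list alone). The export pump Abcb11 was at -0.69 ± 0.085 and the uptake carrier Slc10a1 at -0.62 ± 0.12. The bile acid list had a median log2 fold change of -0.32 (camera adjusted p = 0.0049; adjusted p = 0.394 with an estimated correlation). Of 32 nuclear genes of the respiratory chain, 0 rose, 3 fell and 29 did not pass (0 higher and 1 lower when adjusted over the list alone). Cox6c was at -0.40 ± 0.089. The call of Cox6c ended with total-count scaling (adjusted p = 0.051). The respiratory chain list had a median log2 fold change of -0.14 (camera adjusted p = 0.00011; adjusted p = 0.311 with an estimated correlation).

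Further lists were called downward with fewer or mixed members. Of 18 circadian clock genes, 0 rose, 6 fell and 12 did not pass (1 higher and 9 lower when adjusted over the list alone). Per1 was at -1.13 ± 0.15 and Nr1d1 at -1.36 ± 0.20. The clock list had a median log2 fold change of -0.26 (camera Benjamini-Hochberg adjusted p = 0.00671; adjusted p = 0.219 with an estimated correlation). Of 21 lipoprotein genes, 2 rose, 9 fell and 10 did not pass (2 higher and 9 lower when adjusted over the list alone). Lpl, the lipoprotein lipase, was at 1.59 ± 0.26 and the hepatic lipase Lipc at -0.65 ± 0.11. The lipoprotein list had a median log2 fold change of -0.26 (camera adjusted p = 0.00927; adjusted p = 0.341 with an estimated correlation). Of 12 heat shock genes, 0 rose, 5 fell and 7 did not pass (0 higher and 5 lower when adjusted over the list alone). Hspa8 was at -1.02 ± 0.11. The heat shock list had a median log2 fold change of -0.29 (camera adjusted p = 0.00927; adjusted p = 0.518 with an estimated correlation), and the list's call ended without AdipoRonPEG5 1 (adjusted p = 0.0838) or without vehicle 3 and AdipoRonPEG5 1 together (adjusted p = 0.0617). Of 21 glycolysis and glycogen genes, 1 rose, 8 fell and 12 did not pass (3 higher and 9 lower when adjusted over the list alone). The fructose kinase Khk was at -0.67 ± 0.099 and Pfkfb3 at -1.86 ± 0.28. The glycolysis list had a median log2 fold change of -0.16 (camera adjusted p = 0.0282; adjusted p = 0.645 with an estimated correlation), and the list's call ended without vehicle 1 (adjusted p = 0.0672) or without AdipoRonPEG5 1 (adjusted p = 0.112). Of 4 adipose genes, 0 rose, 1 fell and 3 did not pass (0 higher and 4 lower when adjusted over the list alone). Cfd was at -4.12 ± 1.20 (-2.14 without vehicle 1, -5.50 without AdipoRonPEG5 2). The call of Cfd ended without vehicle 1, AdipoRonPEG5 1, AdipoRonPEG5 2 or AdipoRonPEG5 3, or with limma-voom, or with a replicate block (adjusted p from 0.080 to 0.253). The adipose list had a median log2 fold change of -0.95 (camera adjusted p = 0.0393; adjusted p = 0.394 with an estimated correlation), and the list's call ended without vehicle 1, AdipoRon 1, AdipoRonPEG5 1 or AdipoRonPEG5 3 (adjusted p from 0.0526 to 0.108). In lists that did not pass, the PPAR-alpha and fatty acid oxidation genes had 2 rises and 0 falls among 30, the AMPK and PGC-1 genes 2 and 0 among 19, and the insulin and IGF genes 2 and 2 among 16. The cholesterol synthesis genes had 0 rises and 3 falls among 24, and the growth hormone target genes 2 and 3 among 19, with Cyp4a12a at 1.24 ± 0.16 and Mup3 at -0.81 ± 0.12.

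Further called members of the lists are named here with log2 fold changes ± SE. The calls of Socs2 (1.52 ± 0.27), Ucp2 (1.63 ± 0.21), mt-Nd1 (0.53 ± 0.10), Cth (-0.46 ± 0.093), Hsph1 (-1.06 ± 0.13), Ifi47 (1.67 ± 0.27), Tap1 (1.13 ± 0.19), Cd79a (2.38 ± 0.41), Cyp1a2 (0.73 ± 0.13), Slc1a2 (-0.44 ± 0.093), Pigr (-0.50 ± 0.085), Aldh1a1 (1.14 ± 0.21), Aldh1l2 (2.51 ± 0.47), Atf3 (3.54 ± 0.73), Shmt2 (-0.41 ± 0.086), Derl3 (0.93 ± 0.18), Bag3 (-0.77 ± 0.15) and Mup2 (-1.55 ± 0.25) held with each library left out in turn. Calls that ended with 1 to 3 of the 9 libraries left out in turn were those of Cyp4a31 (1.37 ± 0.31, lost without AdipoRonPEG5 3), Insig1 (-0.94 ± 0.21, lost without AdipoRonPEG5 2), Pik3r1 (-0.39 ± 0.093, lost without vehicle 1, vehicle 2 or AdipoRonPEG5 2), Ndufb5 (-0.28 ± 0.076, lost without vehicle 2, AdipoRonPEG5 2 or AdipoRonPEG5 3), Timp1 (2.55 ± 0.57, lost without vehicle 1 or AdipoRonPEG5 2), Krt8 (0.45 ± 0.11, lost without vehicle 2 or AdipoRonPEG5 2), Jun (2.70 ± 0.61, lost without AdipoRonPEG5 3), Col1a2 (0.78 ± 0.19, lost without vehicle 2 or AdipoRonPEG5 2), Phgdh (2.12 ± 0.49, lost without vehicle 1 or AdipoRonPEG5 3) and Igfbp2 (-0.43 ± 0.12, lost without vehicle 2, AdipoRonPEG5 1 or AdipoRonPEG5 3). The calls of Ehhadh (0.77 ± 0.23), Prkaa2 (0.26 ± 0.077), mt-Nd3 (-0.39 ± 0.11), Il6ra (-0.68 ± 0.19), Cdh5 (0.68 ± 0.18), Rps19 (0.27 ± 0.079), Cd4 (-1.40 ± 0.43), Nr1i2 (-0.30 ± 0.081), Jund (0.38 ± 0.11), Mthfd2 (1.14 ± 0.31), Baat (-0.27 ± 0.071), Slc27a5 (-0.32 ± 0.087), Slco1a4 (-1.49 ± 0.42), Ndufa1 (-0.26 ± 0.080), Pltp (0.84 ± 0.24), Hsp90aa1 (-0.36 ± 0.10), Dnajb1 (-0.49 ± 0.15), Pgk1 (0.27 ± 0.078), Sesn3 (0.60 ± 0.17), Stard4 (-0.38 ± 0.11) and Hsd3b5 (-1.05 ± 0.27) ended with 4 or more of the 9 libraries left out in turn. Of all these genes, Cd4, Col1a2, Aldh1a1, Nr1i2, Jund, Aldh1l2, Atf3, Phgdh, Mthfd2, Shmt2, Derl3, Baat, Slc27a5, Slco1a4, Ndufa1, Pltp, Bag3, Hsp90aa1, Dnajb1, Pgk1, Sesn3, Igfbp2, Stard4, Mup2 and Hsd3b5 fall outside the naming rule and were added after their values were seen, since counts of 5 or fewer hold them. With 1 library left out, values moved by more than 1.5-fold for Cd79a (3.07 without vehicle 1), Jun (1.98 without AdipoRonPEG5 3) and Atf3 (2.12 without AdipoRonPEG5 3). Median, mean and direction of the test differed in sign for lists that did not pass: AMPK subunits and PGC-1 programme (median -0.054, mean 0.029, test downward), Acute phase proteins (median -0.030, mean 0.023, test upward), Cholangiocytes and gallbladder (median 0.11, mean -0.021, test upward) and Pericentral hepatocyte genes (median -0.055, mean 0.052, test downward).

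In all, edgeR called 2260 of 13151 genes between AdipoRonPEG5 and vehicle, 1256 higher and 1004 lower; 585 of the higher and 172 of the lower genes differed by at least 2-fold. The 3 libraries of one group lay entirely above or below those of the other for 4634 genes (35.2%, where chance gives 10%). With total-count scaling the split was 1700 higher and 584 lower, and without the high acute phase libraries vehicle 3 and AdipoRonPEG5 1, 1945 genes were called. The number of calls was 1337 without vehicle 2, 1348 without AdipoRonPEG5 2 and 1438 without AdipoRonPEG5 3. camera called 22 of 38 lists; with an estimated correlation it called 0, and 7 at an unadjusted p under 0.05.

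The second comparison asked what the parent compound does. Of the genes named for the size of their rise with AdipoRon, the first 3, Cd300e, Marco and Fpr2, are genes of myeloid cells. Marco went from 3.7 ± 1.42 CPM in vehicle to 60.0 ± 24.2 CPM (SD, n = 3; log2 fold change 4.05 ± 0.31 (SE), edgeR Benjamini-Hochberg adjusted p = 0.000389), and Cd300e from 0.252 ± 0.0888 to 5.27 ± 1.88 CPM (4.26 ± 0.36, adjusted p = 0.000622). Cish, an inhibitor of cytokine signalling that STAT5 induces, went from 2.23 ± 1.33 to 16.5 ± 5.43 CPM (2.95 ± 0.34, adjusted p = 0.00229). Bcl6 fell from 107 ± 5.57 to 33.8 ± 15.8 CPM (-1.66 ± 0.25, adjusted p = 0.0059). The formyl peptide receptor Fpr2 (3.90 ± 0.56), the Toll-like receptor Tlr1 (2.86 ± 0.36), the myeloid lectin Clec4a1 (2.60 ± 0.39) and Spic, a transcription factor of tissue macrophages (2.60 ± 0.28), were among the 8 largest rises. Onecut1, a hepatocyte transcription factor, was at 2.63 ± 0.48, but the call ended with only the 2 groups fitted (adjusted p = 0.0504) or without vehicle 1 (adjusted p = 0.0608). After Bcl6 the falls were smaller: Gpr98 -1.14 ± 0.20, Arl4d -1.06 ± 0.18, Tmem39a -1.05 ± 0.16 and Setd4 -1.0 ± 0.17. Zfp9 was at -1.44 ± 0.26 and Atxn1 at -1.35 ± 0.30. The call of Zfp9 ended without AdipoRon 2 (adjusted p = 0.051) and the call of Atxn1 ended without AdipoRon 2 or AdipoRon 3, or with only the 2 groups fitted, or with a replicate block (adjusted p from 0.0598 to 0.090). For Esrrg (-1.16 ± 0.25), the call ended without vehicle 1, vehicle 2, AdipoRon 1, AdipoRon 2 or AdipoRon 3, or with only the 2 groups fitted, or with a replicate block (adjusted p from 0.0563 to 0.090).

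Immune lists were called upward with AdipoRon as well (values in parentheses are log2 fold changes ± SE). Of 18 macrophage and Kupffer cell genes, 11 rose, 0 fell and 7 did not pass (14 higher and 0 lower when adjusted over the list alone). Cd5l was at 1.77 ± 0.19 and Emr1, which encodes the F4/80 antigen, at 2.17 ± 0.26. The macrophage list had a median log2 fold change of 1.26 (camera Benjamini-Hochberg adjusted p = 5.47e-11; adjusted p = 0.40 with an estimated correlation). Of 22 interferon response genes, 11 rose, 0 fell and 11 did not pass (17 higher and 0 lower when adjusted over the list alone). Called members include Ifit2 (1.21 ± 0.17) and Oas2 (0.96 ± 0.17). The interferon list had a median log2 fold change of 0.70 (camera adjusted p = 1.41e-10; adjusted p = 0.40 with an estimated correlation). Of 11 lymphocyte genes, 2 rose, 0 fell and 9 did not pass (6 higher and 0 lower when adjusted over the list alone). Cd3e, a T cell receptor component, had 34 counts over the AdipoRon libraries against 3 over the vehicle libraries, a ratio of 16.2 (95% interval 5.09 to 82.3). Its log2 fold change of 3.74 ± 0.76 became 3.11 without vehicle 1. The call of Cd3e ended without vehicle 1, vehicle 2, AdipoRon 1 or AdipoRon 3 (adjusted p from 0.0513 to 0.0989). For Cd79b (1.88 ± 0.47; 2.77 without vehicle 1) the call ended without any 1 of the 9 libraries, or with limma-voom, or with a replicate block, or without vehicle 3 and AdipoRonPEG5 1 together (adjusted p from 0.0516 to 0.131). The lymphocyte list had a median log2 fold change of 1.34 (camera adjusted p = 0.000199; adjusted p = 0.40 with an estimated correlation), and the list's call ended with a filter at a mean of 1 CPM (adjusted p = 0.157). Of 16 stellate cell and matrix genes, 1 rose, 0 fell and 15 did not pass (3 higher and 0 lower when adjusted over the list alone). Tgfb1 was at 0.78 ± 0.14. The stellate list had a median log2 fold change of 0.38 (camera adjusted p = 0.00197; adjusted p = 0.538 with an estimated correlation). Of 14 antigen presentation genes, edgeR called 0, with 8 at an unadjusted p under 0.05, 2 called by DESeq2 and 0 by limma-voom (8 higher and 0 lower when adjusted over the list alone). The members with the lowest p, Tap1 at 0.64 ± 0.19 and Ciita at 1.27 ± 0.41, had adjusted p = 0.071 and 0.0967. The antigen presentation list had a median log2 fold change of 0.81 (camera adjusted p = 0.00752; adjusted p = 0.866 with an estimated correlation), and the list's call ended without AdipoRon 1 (adjusted p = 0.221). Of 16 cell cycle genes, 3 rose, 0 fell and 13 did not pass (3 higher and 0 lower when adjusted over the list alone). Top2a was at 1.84 ± 0.37. The call of Top2a ended without vehicle 1, AdipoRon 1 or AdipoRon 2 (adjusted p from 0.0522 to 0.0862). The cell cycle list had a median log2 fold change of 0.40 (camera adjusted p = 0.00842; adjusted p = 0.40 with an estimated correlation).

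Lists called downward with AdipoRon had small median changes. Of 20 ribosomal protein genes, 0 rose, 3 fell and 17 did not pass (0 higher and 16 lower when adjusted over the list alone). Rpl37 was at -0.36 ± 0.086. The call of Rpl37 ended without vehicle 2, vehicle 3, AdipoRon 1, AdipoRon 2, AdipoRon 3 or AdipoRonPEG5 2, or with total-count scaling, or with only the 2 groups fitted, or with a replicate block, or with a length trend removed, or with length and GC trends removed, or without vehicle 3 and AdipoRonPEG5 1 together (adjusted p from 0.0611 to 0.15). The ribosomal list had a median log2 fold change of -0.29 (camera Benjamini-Hochberg adjusted p = 8.34e-09; adjusted p = 0.56 with an estimated correlation). Of 32 nuclear genes of the respiratory chain, 0 rose, 7 fell and 25 did not pass (0 higher and 15 lower when adjusted over the list alone). Ndufa2 was at -0.49 ± 0.087. The respiratory chain list had a median log2 fold change of -0.20 (camera adjusted p = 1.78e-08; adjusted p = 0.40 with an estimated correlation). Of 19 endoplasmic reticulum stress genes, 0 rose, 3 fell and 16 did not pass (0 higher and 9 lower when adjusted over the list alone). Syvn1 was at -0.86 ± 0.20. The call of Syvn1 ended without vehicle 1, vehicle 2, vehicle 3, AdipoRon 2 or AdipoRon 3 (adjusted p from 0.0618 to 0.0979). The ER stress list had a median log2 fold change of -0.38 (camera adjusted p = 3.86e-06; adjusted p = 0.56 with an estimated correlation). Of 21 lipoprotein genes, 2 rose, 0 fell and 19 did not pass (2 higher and 6 lower when adjusted over the list alone). The phospholipid transfer protein Pltp was at 1.22 ± 0.24, against the list's direction. The call of Pltp ended without vehicle 2 or AdipoRon 1, or with only the 2 groups fitted, or without vehicle 3 and AdipoRonPEG5 1 together (adjusted p from 0.0526 to 0.0692). The lipoprotein list had a median log2 fold change of -0.20 (camera adjusted p = 0.0189; adjusted p = 0.56 with an estimated correlation), and the list's call ended without vehicle 1, AdipoRon 1 or AdipoRon 2, or with a length trend removed, or with length and GC trends removed (adjusted p from 0.0661 to 0.118). With AdipoRon, log2 fold changes went with gene length across genes (Spearman's rho 0.295). With a length trend removed, the medians were -0.17 for the ribosomal, -0.076 for the respiratory chain, -0.38 for the ER stress and -0.15 for the lipoprotein list, of which only the last did not pass (camera adjusted p = 0.118), and 0 ribosomal protein genes were called lower. Median log2 fold changes were 0.12 for fatty acid and triglyceride synthesis, -0.025 for amino acid catabolism and -0.058 for the PPAR-alpha list, and these lists did not pass (adjusted p = 0.22, 0.214 and 0.559). In lists that did not pass, the glycolytic enzyme gene Pklr was at 0.74 ± 0.13, Gstm3 at 1.01 ± 0.14 and Ddit3 at -0.72 ± 0.12, each called by edgeR.

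Further called members of the lists are named here with log2 fold changes ± SE. Calls that ended with 1 to 3 of the 9 libraries left out in turn were those of Cox5b (-0.38 ± 0.072, lost without vehicle 2 or AdipoRon 1), Cox4i1 (-0.37 ± 0.072, lost without vehicle 2, AdipoRon 1 or AdipoRon 2), Hmox1 (1.17 ± 0.23, lost without vehicle 1, vehicle 2 or AdipoRon 1), Bag3 (-0.72 ± 0.15, lost without vehicle 1, vehicle 2 or AdipoRon 2), Gbp2 (1.35 ± 0.25, lost without vehicle 2) and Mki67 (2.52 ± 0.51, lost without vehicle 1, vehicle 2 or AdipoRon 1). The calls of Lpl (1.21 ± 0.27), Nr3c1 (0.40 ± 0.086), Derl3 (-0.78 ± 0.19), Herpud1 (-0.63 ± 0.16), Nr1d1 (-0.80 ± 0.20), Cyp4a12a (0.72 ± 0.16), Myc (2.26 ± 0.51), Rplp1 (-0.43 ± 0.11), Rps15 (-0.31 ± 0.078) and Cdk1 (1.56 ± 0.37) ended with 4 or more of the 9 libraries left out in turn. Of all these genes, Cdk1 falls outside the naming rule and was added after its values were seen, since counts of 5 or fewer hold it. Median, mean and direction of the test differed in sign for lists that did not pass: Mitochondrially encoded genes (median 0.034, mean 0.026, test downward) and p53 and growth arrest (median 0.0051, mean 0.046, test downward).

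In all, edgeR called 684 genes between AdipoRon and vehicle, 500 higher and 184 lower, of which 270 and 13 differed by at least 2-fold. Groups did not overlap for 3524 genes (26.8%, where chance gives 10%). With total-count scaling the median log2 fold change of all genes was 0.104, against 0.0057 with TMM, and edgeR called 883 higher and 64 lower genes. With a length trend removed the split was 425 higher and 98 lower, and with a replicate block 365 and 79; without vehicle 3 and AdipoRonPEG5 1, 586 genes were called. Calls numbered 279 without vehicle 1, 250 without vehicle 2, 367 without AdipoRon 1, 292 without AdipoRon 2, 450 without AdipoRonPEG5 2 and 325 from a fit of the 2 groups alone. In simulated data with these depths the test recovered 40.3%, 68.7% and 92.4% of changes of 1.5, 2 and 4-fold, with 6.94% false calls. camera called 10 lists (16 without vehicle 3); with an estimated correlation it called 0, and 4 at an unadjusted p under 0.05. Of the 10 possible splits of these 6 libraries into 3 and 3, 9 gave at least as many called lists as the real one, itself included, and only the real one gave as many called genes.

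The third comparison set the PEGylated analog directly against the parent compound after the same 5 days of injections; equal doses are labelled but not certain. The glutathione transferase genes Gsta1 and Gstm3 were higher with AdipoRonPEG5. Gsta1 stood at 0.295 ± 0.165 CPM with AdipoRon and 491 ± 49.0 CPM with AdipoRonPEG5 (SD, n = 3; log2 fold change 10.71 ± 0.30 (SE), edgeR Benjamini-Hochberg adjusted p = 1.71e-08), and Gstm3 at 20.2 ± 3.0 and 696 ± 45.3 CPM (log2 difference 5.11, 95% confidence interval 4.77 to 5.45). Scd1 was lower: it stood at 1514 ± 627 CPM with AdipoRon and 141 ± 56.1 CPM with AdipoRonPEG5 (-3.42, 95% confidence interval -4.27 to -2.58; adjusted p = 0.00109). Of macrophage genes, the log2 difference was 0.21 (95% confidence interval -0.35 to 0.76) for Marco, 0.21 (95% confidence interval -0.19 to 0.62) for Cd5l and 0.090 (95% confidence interval -0.41 to 0.59) for Emr1, none of which passed. A miss does not show that the compounds act alike on these genes, since the intervals leave room for a difference.

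Also among the largest rises were the glutathione transferases Gsta2 (4.10 ± 0.41) and Gstm1 (3.44 ± 0.20), the transporter Abcc12 (3.59 ± 0.35) and the glucuronosyltransferase Ugt2b37 (3.46 ± 0.56; 4.54 without AdipoRon 2). The metallothionein Mt2, which binds zinc and copper, was at 3.90 ± 0.72 (2.49 without AdipoRonPEG5 1), and Cyp2a4 at 6.54 ± 0.98 (5.22 without AdipoRonPEG5 2, 7.94 without AdipoRon 3). The call of Cyp2a4 ended with limma-voom (adjusted p = 0.11). Falls were led by Mup9 at -5.03 ± 1.04, Mup17 at -3.70 ± 0.77, Cyp3a11 at -3.60 ± 0.51 and, after Scd1, Mup19 at -3.07 ± 0.40 (-3.86 without AdipoRonPEG5 1). For Mup9, the call ended without AdipoRonPEG5 1, AdipoRonPEG5 2 or AdipoRonPEG5 3, or with limma-voom (adjusted p from 0.0721 to 0.168), and the value was -3.65 without AdipoRon 2. For Mup17, the call ended without AdipoRonPEG5 1 (adjusted p = 0.0814) or without AdipoRonPEG5 3 (adjusted p = 0.0888). Its value was -2.55 without AdipoRon 2 and -4.39 without AdipoRonPEG5 2. Mycn was at -1.95 ± 0.26. Chrna4 (-2.96 ± 0.59) and Ptgds (-2.04 ± 0.38) were less secure: the call of Chrna4 ended without AdipoRon 1, AdipoRon 3 or AdipoRonPEG5 3, or with a replicate block (adjusted p from 0.053 to 0.0686), with a value of -3.83 without AdipoRonPEG5 2. The call of Ptgds ended without AdipoRonPEG5 1, AdipoRonPEG5 2 or AdipoRonPEG5 3 (adjusted p from 0.0505 to 0.0619).

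Lists called higher with AdipoRonPEG5 than with AdipoRon were these. Of 14 NRF2 genes, 7 rose, 0 fell and 7 did not pass (8 higher and 0 lower when adjusted over the list alone). Called members include Cbr3 (3.18 ± 0.26) and Abcc4 (2.51 ± 0.22). The NRF2 list had a median log2 fold change of 0.83 (camera Benjamini-Hochberg adjusted p = 2.80e-09; adjusted p = 0.177 with an estimated correlation). Of 20 ribosomal protein genes, 12 rose, 0 fell and 8 did not pass (19 higher and 0 lower when adjusted over the list alone). Rps19 was at 0.57 ± 0.080. The ribosomal list had a median log2 fold change of 0.38 (camera adjusted p = 5.57e-13; adjusted p = 0.477 with an estimated correlation). Of 14 antigen presentation genes, 1 rose, 0 fell and 13 did not pass (10 higher and 0 lower when adjusted over the list alone). Ciita was at 1.34 ± 0.34. The call of Ciita ended without vehicle 2, AdipoRon 2, AdipoRon 3, AdipoRonPEG5 1, AdipoRonPEG5 2 or AdipoRonPEG5 3, or with a replicate block, or without vehicle 3 and AdipoRonPEG5 1 together (adjusted p from 0.0522 to 0.138). The antigen presentation list had a median log2 fold change of 0.94 (camera adjusted p = 1.66e-05; adjusted p = 0.488 with an estimated correlation). Of 18 macrophage genes, 2 rose, 0 fell and 16 did not pass (5 higher and 0 lower when adjusted over the list alone). Ccr2, the receptor by which monocytes are recruited, was at 1.47 ± 0.22. The macrophage list had a median log2 fold change of 0.35 (camera adjusted p = 5.25e-05; adjusted p = 0.488 with an estimated correlation). Of 30 PPAR-alpha and fatty acid oxidation genes, 1 rose, 0 fell and 29 did not pass (1 higher and 0 lower when adjusted over the list alone). The omega-hydroxylase gene Cyp4a31 was at 2.0 ± 0.33. The PPAR-alpha list had a median log2 fold change of 0.22 (camera adjusted p = 0.00524; adjusted p = 0.737 with an estimated correlation), and the list's call ended without AdipoRon 2 (adjusted p = 0.155). Of 17 ATF4 genes, 5 rose, 1 fell and 11 did not pass (6 higher and 2 lower when adjusted over the list alone). Psat1 was at 2.94 ± 0.37. The ATF4 list had a median log2 fold change of 0.29 (camera adjusted p = 0.0177; adjusted p = 0.488 with an estimated correlation), and the list's call ended with a filter at a mean of 1 CPM (adjusted p = 0.149) or without AdipoRon 3 (adjusted p = 0.0745).

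In 3 more lists called upward, single libraries decided the call. Of 24 acute phase genes, 1 rose, 1 fell and 22 did not pass (1 higher and 1 lower when adjusted over the list alone), and Saa1 was at 1952 CPM in AdipoRonPEG5 1 against 173 and 207 CPM in the other libraries of its group. The acute phase list had a median log2 fold change of 0.46 (camera Benjamini-Hochberg adjusted p = 0.0289; adjusted p = 0.761 with an estimated correlation), and the list's call ended without AdipoRon 1, AdipoRon 3 or AdipoRonPEG5 1, or without vehicle 3 and AdipoRonPEG5 1 together (adjusted p from 0.0645 to 0.318). Of 7 erythroid genes, edgeR called 0, with 1 at an unadjusted p under 0.05, 0 called by DESeq2 and 0 by limma-voom (0 higher and 0 lower when adjusted over the list alone). The erythroid list had a median log2 fold change of 0.80 (camera adjusted p = 0.0339; adjusted p = 0.687 with an estimated correlation), and the list's call ended without AdipoRon 1, AdipoRonPEG5 1 or AdipoRonPEG5 3, or with length and GC trends removed (adjusted p from 0.053 to 0.136). Of 11 lymphocyte genes, edgeR called 0, with 5 at an unadjusted p under 0.05, 1 called by DESeq2 and 0 by limma-voom (0 higher and 0 lower when adjusted over the list alone). The lymphocyte list had a median log2 fold change of 0.58 (camera adjusted p = 0.0427; adjusted p = 0.488 with an estimated correlation), and the list's call ended without AdipoRon 2, AdipoRon 3, AdipoRonPEG5 1 or AdipoRonPEG5 3, or with a filter at a mean of 1 CPM, or with a length trend removed, or with length and GC trends removed, or without vehicle 3 and AdipoRonPEG5 1 together (adjusted p from 0.0619 to 0.542).

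Metabolic and clock lists were called lower with AdipoRonPEG5 than with AdipoRon. Of 23 fatty acid and triglyceride synthesis genes, 0 rose, 11 fell and 12 did not pass (0 higher and 17 lower when adjusted over the list alone). Called members include Thrsp (-1.89, 95% confidence interval -2.12 to -1.65) and Elovl6 (-1.42, 95% confidence interval -1.74 to -1.10). The lipogenesis list had a median log2 fold change of -0.61 (camera Benjamini-Hochberg adjusted p = 2.80e-09; adjusted p = 0.236 with an estimated correlation), beside an adipose median of -0.91. Of 17 gluconeogenesis genes, 0 rose, 5 fell and 12 did not pass (0 higher and 9 lower when adjusted over the list alone). Klf15 was at -0.69 ± 0.12. The gluconeogenesis list had a median log2 fold change of -0.37 (camera adjusted p = 1.46e-06; adjusted p = 0.236 with an estimated correlation). Of 23 amino acid catabolism genes, 0 rose, 5 fell and 18 did not pass (0 higher and 15 lower when adjusted over the list alone). The proline-degrading enzyme Prodh was at -0.52 ± 0.095. The call of Prodh ended without AdipoRon 3 (adjusted p = 0.0521) or without AdipoRonPEG5 3 (adjusted p = 0.0561). The amino acid list had a median log2 fold change of -0.31 (camera adjusted p = 4.34e-06; adjusted p = 0.236 with an estimated correlation). Of 18 circadian clock genes, 0 rose, 6 fell and 12 did not pass (0 higher and 11 lower when adjusted over the list alone). Per2 was at -0.67 ± 0.11. The clock list had a median log2 fold change of -0.36 (camera adjusted p = 1.28e-05; adjusted p = 0.0829 with an estimated correlation). Of 21 glycolysis genes, 0 rose, 5 fell and 16 did not pass (2 higher and 8 lower when adjusted over the list alone). Called members include Pklr (-1.26, 95% confidence interval -1.55 to -0.97) and Khk (-0.65, 95% confidence interval -0.87 to -0.43). The glycolysis list had a median log2 fold change of -0.26 (camera adjusted p = 0.00686; adjusted p = 0.606 with an estimated correlation). Of 17 bile acid genes, 0 rose, 2 fell and 15 did not pass (0 higher and 3 lower when adjusted over the list alone). Abcb11 was at -0.50 ± 0.085. The bile acid list had a median log2 fold change of -0.19 (camera adjusted p = 0.0289; adjusted p = 0.606 with an estimated correlation), and the list's call ended without AdipoRon 1, AdipoRon 3 or AdipoRonPEG5 1, or without vehicle 3 and AdipoRonPEG5 1 together (adjusted p from 0.0595 to 0.135). Of 17 periportal genes, 0 rose, 2 fell and 15 did not pass (0 higher and 3 lower when adjusted over the list alone). The periportal list had a median log2 fold change of -0.20 (camera adjusted p = 0.0041; adjusted p = 0.465 with an estimated correlation). Of 4 adipose genes, edgeR called 0, with 2 at an unadjusted p under 0.05, 1 called by DESeq2 and 0 by limma-voom (0 higher and 2 lower when adjusted over the list alone). The adipose list had a median log2 fold change of -0.91 (camera adjusted p = 0.0289; adjusted p = 0.488 with an estimated correlation), and the list's call ended without AdipoRon 3, AdipoRonPEG5 1 or AdipoRonPEG5 3 (adjusted p from 0.0567 to 0.079). In lists that did not pass, Oas2 was at -1.33 ± 0.17, Hspa8 at -0.78 ± 0.11, Derl3 at 1.71 ± 0.18, Asah1 at 0.58 ± 0.086 and mt-Nd3 at -0.72 ± 0.11, each called by edgeR.

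Further called members of the lists are named here with log2 fold changes ± SE. The calls of Hsph1 (-0.73 ± 0.13), Slc1a2 (-0.73 ± 0.093), Cyp1a2 (0.79 ± 0.13) and Pygl (-0.57 ± 0.098) held with each library left out in turn. Calls that ended with 1 to 3 of the 9 libraries left out in turn were those of Gpnmb (2.72 ± 0.52, lost without AdipoRon 1, AdipoRon 3 or AdipoRonPEG5 2), Per3 (-0.54 ± 0.096, lost without AdipoRonPEG5 3) and Rps15 (0.42 ± 0.078, lost without AdipoRon 1, AdipoRonPEG5 1 or AdipoRonPEG5 2). The calls of Insig1 (-0.84 ± 0.21), Slc10a1 (-0.55 ± 0.12), Fbp1 (-0.52 ± 0.10), Creb1 (-0.37 ± 0.085), Ppargc1b (-1.05 ± 0.23), Ucp2 (0.85 ± 0.20), Cps1 (-0.55 ± 0.12), Gls2 (-0.43 ± 0.093), Herpud1 (-0.77 ± 0.16), Aldh1l2 (2.5 ± 0.48), C3 (0.67 ± 0.15), Il6ra (-0.76 ± 0.19), Rsad2 (-0.62 ± 0.15), Krt8 (0.45 ± 0.11), Nr1d2 (-0.37 ± 0.077), Mup2 (-1.22 ± 0.25), Mup3 (-0.56 ± 0.12), Ccnd1 (-0.97 ± 0.25), Jun (3.06 ± 0.63), Phgdh (2.34 ± 0.52), Atf3 (2.82 ± 0.69), Gdf15 (2.05 ± 0.52), Ddit3 (-0.52 ± 0.13), Slc37a4 (-0.42 ± 0.097), Tat (-1.37 ± 0.34), Otc (-0.40 ± 0.090), Asl (-0.44 ± 0.11) and Slc2a2 (-0.57 ± 0.13) ended with 4 or more of the 9 libraries left out in turn. Of all these genes, Phgdh, Atf3, Gdf15, Ddit3, Slc37a4, Tat, Otc, Asl, Pygl and Slc2a2 fall outside the naming rule and were added after their values were seen, since counts of 5 or fewer hold them. With 1 library left out, values moved by more than 1.5-fold for Gpnmb (3.47 without AdipoRon 2), Jun (2.35 without AdipoRonPEG5 3), Atf3 (1.42 without AdipoRonPEG5 3) and Gdf15 (1.05 without AdipoRonPEG5 3). Median, mean and direction of the test differed in sign for lists that did not pass: Cholesterol synthesis and uptake (median -0.044, mean 0.0064, test upward) and Pericentral hepatocyte genes (median -0.083, mean 0.0069, test downward).

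In all, edgeR called 709 genes between the compounds, 352 higher and 357 lower with AdipoRonPEG5, and 84 and 68 of these differed by at least 2-fold. Groups did not overlap for 3705 genes (28.2%, where chance gives 10%). Total-count scaling gave 343 higher and 381 lower, and 654 genes were called without vehicle 3 and AdipoRonPEG5 1. Leaving out 1 of the 6 libraries compared gave 345 (AdipoRon 1), 415 (AdipoRon 2), 306 (AdipoRon 3), 273 (AdipoRonPEG5 1), 233 (AdipoRonPEG5 2) and 253 calls (AdipoRonPEG5 3). In simulated data the test recovered 40.3%, 70.1% and 98.5% of changes of 1.5, 2 and 4-fold, with 7.33% false calls. camera called 17 lists; with an estimated correlation it called 0, and 5 at an unadjusted p under 0.05.

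Effects of the 2 compounds against vehicle ran partly in parallel. Of the 500 genes that rose with AdipoRon, 395 also rose with AdipoRonPEG5, where independent lists would share 47.8; of the 184 that fell, 89 fell with both (independent lists, 14.0). In 50 simulations without change but with shared vehicle libraries, at most 1 gene rose and at most 1 fell with both. Independent lists leave out the shared libraries and these simulations the effects, so that part of the excess may come from those libraries. Marco, Cd5l, Tgfb1 and Bcl6 were among the 484 genes called with both in the same direction, of which 18 also differed between the compounds. Of the 2260 genes called with AdipoRonPEG5, 496, Gsta1, Thrsp, Scd1 and Cyp3a11 among them, were also called in the same direction against AdipoRon. Log2 fold changes of both comparisons correlated across the 13151 genes, which are not independent replicates, with Pearson's r = 0.675 and Spearman's rho = 0.60. Both comparisons use the same 3 vehicle libraries. Simulated groups without change that share them gave r = 0.503 on average and at most 0.546 in 100 simulations. Between group means the covariance was 0.186, against 0.0416 simulated. Both simulated values may be too low if many genes of a shared library deviate together (not tested).

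**Figure D2:**
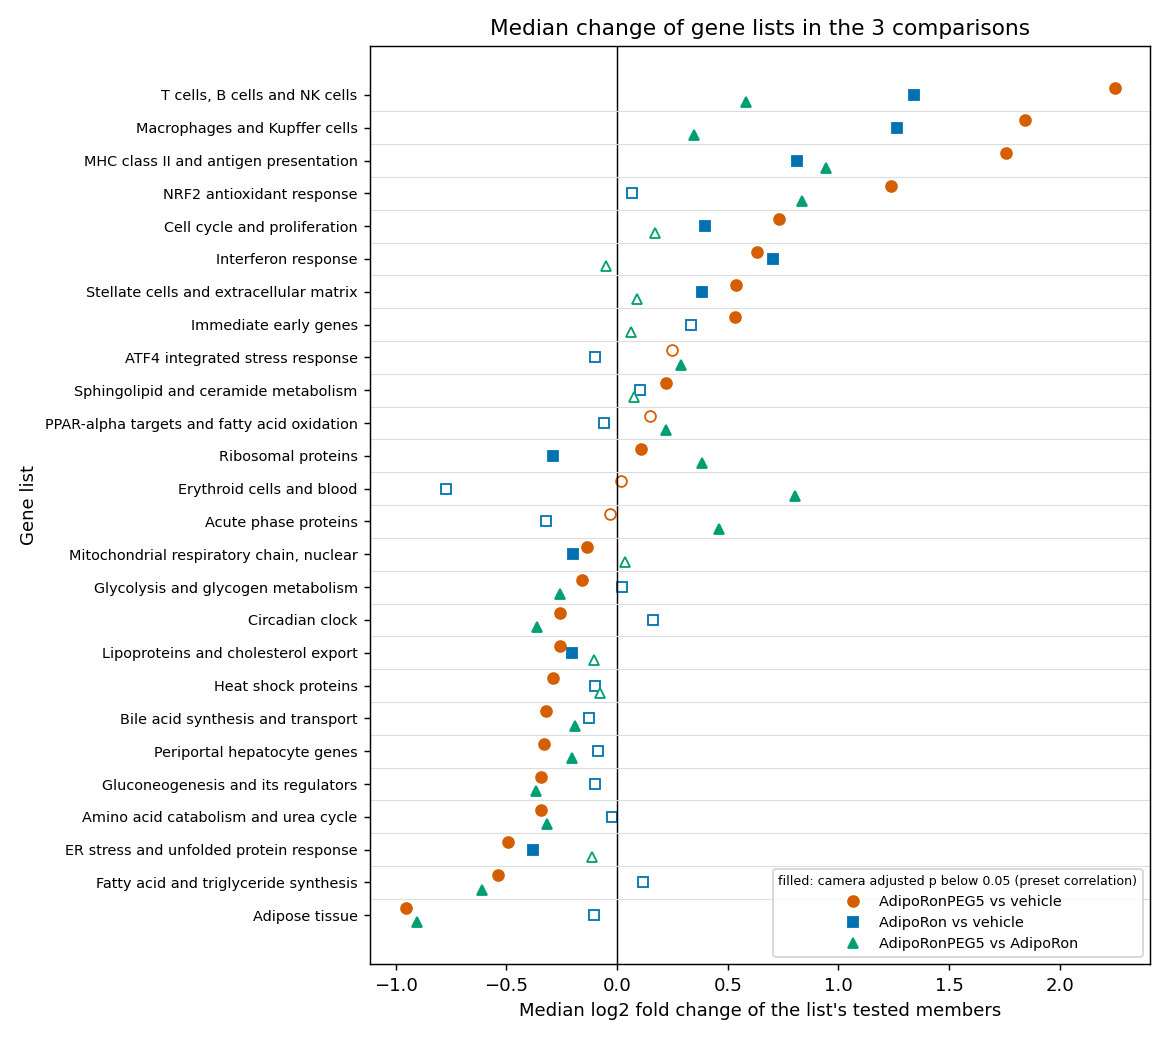
Median log2 fold change (horizontal axis) of the 26 gene lists called in at least 1 comparison, 1 point per comparison, filled where camera's Benjamini-Hochberg adjusted p was below 0.05. Macrophage medians lay at 1.84 and 1.26 against vehicle, while the NRF2 and lipogenesis medians lay apart from 0 with AdipoRonPEG5 (1.24 and -0.54).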

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

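The tests chosen only after the result was seen are those of a larger macrophage share, of a smaller hepatocyte share and of RNA from additional macrophages, the settings that remove length or GC trends or thin vehicle 1, and the joint removal of vehicle 3 and AdipoRonPEG5 1; the test of direct STAT5 targets, given further on, was also chosen then. For 3 genes the calls against vehicle ran in opposite directions with the 2 compounds, and the direct test of the difference passed. Cyp2c67, chosen after its values were seen, had log2 fold changes of 0.71 with AdipoRonPEG5 and -0.56 with AdipoRon (difference 1.27, 95% confidence interval 0.98 to 1.56, edgeR Benjamini-Hochberg adjusted p = 0.000654). Derl3, which acts in the disposal of misfolded proteins, had 0.93 and -0.78 (difference 1.71, 95% confidence interval 1.30 to 2.11, adjusted p = 0.000817), and for AdipoRon against vehicle the call ended without vehicle 1, vehicle 3, AdipoRon 1, AdipoRon 2, AdipoRonPEG5 1, AdipoRonPEG5 2 or AdipoRonPEG5 3, or with only the 2 groups fitted, or with a length trend removed, or without vehicle 3 and AdipoRonPEG5 1 together (adjusted p from 0.0522 to 0.121). Pklr had -0.52 and 0.74 (difference -1.26, 95% confidence interval -1.55 to -0.97, adjusted p = 0.000654), and for AdipoRonPEG5 against vehicle the call ended without vehicle 1, vehicle 2, AdipoRonPEG5 1 or AdipoRonPEG5 2 (adjusted p from 0.0626 to 0.0731).

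Each comparison of 3 against 3 libraries allows 10 splits, too few for a share under 0.05. The real split gave the most called genes in each comparison (1 of 10 splits as large; 2260, 684 and 709 genes), and the highest other split gave 0. For lists the real counts were 22, 10 and 17, and the highest other splits gave 18, 19 and 15. As many lists as in the real split came from 1, 9 and 1 of the 10 splits, so that camera at its preset correlation calls lists in regrouped libraries too.

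Of 20 ribosomal protein genes, 3 were called lower in AdipoRon than in vehicle livers and 12 higher in AdipoRonPEG5 than in AdipoRon livers (medians -0.29 and 0.38). The list passed in both comparisons at camera's preset correlation and in neither with an estimated correlation (Benjamini-Hochberg adjusted p = 0.56 and 0.477), and the tests that follow use the preset one. These genes are short (median length 1124 against 3032 for all tested genes), and log2 fold changes went with gene length across genes (Spearman's rho 0.295 for AdipoRon against vehicle, -0.207 between the compounds). With a length trend removed from each library, the medians were -0.17 and 0.31, called members went from 3 to 0 and from 12 to 6, and the list passed in both comparisons (camera, higher Benjamini-Hochberg adjusted p = 2.62e-05; 1.26e-05 with GC removed too). Thinning vehicle 1 left the list past the threshold as well (higher adjusted p = 9.41e-09). A length trend may account for part of the difference, and the medians kept their sign after its removal. Whether it accounts for all of it is not decided, since with an estimated correlation the list passed in neither comparison even before the removal. An effect of AdipoRon stays open, untested.

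Of 18 macrophage genes, 16 were called higher with AdipoRonPEG5 and 11 with AdipoRon than with vehicle; of the abundant ones, Cd5l was at 40.1 ± 6.14, 136 ± 43.6 and 158 ± 0.571 CPM and C1qc at 24.1 ± 5.91, 62.2 ± 13.8 and 75.2 ± 5.89 CPM in vehicle, AdipoRon and AdipoRonPEG5 livers. More Kupffer cells alone would raise all their genes alike, but the 9 Kupffer cell genes tested differed in their log2 fold changes, from 0.95 (Clec4f) to 4.26 (Marco) with AdipoRonPEG5 and from 0.73 to 4.05 with AdipoRon (heterogeneity chi-square test on edgeR's estimates and standard errors, larger p = 1.59e-15; without Marco, p = 0.00759 and 0.00428). A smaller share of hepatocytes would raise every other cell type alike. The lymphocyte list (medians 2.25 with AdipoRonPEG5 and 1.34 with AdipoRon) and the stellate cell and matrix list (0.54 and 0.38) were also called upward at the preset correlation, which goes with a smaller share, but not with an estimated correlation (adjusted p = 0.219 and 0.40 for lymphocytes, 0.311 and 0.538 for stellate cells); the lymphocyte calls also ended with a filter at a mean of 1 CPM (adjusted p = 0.151 and 0.157). The endothelial medians were 0.11 and -0.075, with an upper interval bound of at most 0.238, below the macrophage medians of 1.84 and 1.26, so that a smaller share is not the whole cause; a part of it stays open. The list also passed with each vehicle library left out in turn (camera, highest Benjamini-Hochberg adjusted p = 3.29e-09), but with all libraries it did not pass with either compound at adjusted p = 0.223 and 0.40 with an estimated correlation. What stays open, as a hypothesis, is that both compounds may change the number of macrophages, their activity, their kind or several of these. No test here separates them.

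In AdipoRonPEG5 livers, 10 of 20 glutathione transferase genes were called higher and 3 lower than in vehicle livers, and 9 higher and 1 lower than in AdipoRon livers. Of 14 NRF2 genes, 9 and 7 were called higher in these comparisons and 5 and 7 did not pass. Reads shared between paralogs would confine the rise to the transferases, yet the NRF2 list without them (11 genes) still passed between the compounds (camera, Benjamini-Hochberg adjusted p = 2.71e-06; adjusted p = 0.196 with an estimated correlation), with 5 members called higher. How the counts divide among the paralogs themselves was not tested. RNA of additional macrophages would raise the list with AdipoRon too, where macrophage genes were also higher, but there the list did not pass (camera, adjusted p = 0.377), while its member Hmox1 (1.17; lost without vehicle 1, vehicle 2 or AdipoRon 1) and the transferase gene Gstm3 (1.01) were called with AdipoRon, and a part from macrophages, whose median differed by 0.35 between the compounds, stays open. An NRF2 response that may be stronger with AdipoRonPEG5 than with AdipoRon is a hypothesis that stays open, found and tested on the same libraries; a missed threshold does not show that AdipoRon evokes none. Other regulators, such as CAR, PXR and ATF4, were not tested as explanations and stay open. Between the compounds the ATF4 list was called upward (camera, adjusted p = 0.0177, or 0.488 with an estimated correlation). The drug metabolism list (CAR, PXR) did not pass (adjusted p = 0.146), with 5 rises and 1 fall (Cyp3a11, -3.60).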

How the results depend on the processing

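Of the tests compared here, those chosen after the data were seen were the thinned vehicle 1, the removal of length or of length and GC trends, and the joint removal of vehicle 3 and AdipoRonPEG5 1. Of 200 named gene results, 124 kept direction and side of the threshold in all alternatives run, as did 32 of 49 list results, the estimated correlation apart. Other pseudocounts were not tried, since counts were tested. Gene calls stayed within 1.5 times the reported number except for AdipoRon against vehicle with only the 2 groups fitted (325, 12692 genes tested) or a replicate block (444), AdipoRonPEG5 against AdipoRon with the block (338), and with single libraries left out: 1337 to 2334 for AdipoRonPEG5 against vehicle, 250 to 624 for AdipoRon and 233 to 1032 between the compounds. For the block the cause was not tested; the others fit fewer samples. List calls ranged from 18 to 24, 9 to 16 and 12 to 18 with 1 library left out, were 16 for AdipoRon without vehicle 3 and AdipoRonPEG5 1 (the cause was not tested), and were 0, 0 and 0 with an estimated correlation, which widens each list's test (7, 4 and 5 at an unadjusted p under 0.05). Pearson's r between the effects was 0.613 to 0.72 with 1 library left out. Values that changed sign were near 0 and past no threshold: Adipor1 with AdipoRon (-0.063 to 0.041 with 1 library left out), at -0.036 without vehicle 2, -0.063 without AdipoRon 1, -0.014 with length and -0.046 with length and GC trends removed; and Adipor2 with AdipoRon (-0.069 to 0.026 with 1 library left out), at 0.089 with total-count scaling, 0.026 without vehicle 3, 0.012 without AdipoRon 2 and 0.028 without vehicle 3 and AdipoRonPEG5 1 (the cause was not tested). With voom, the calls of Mup9 against vehicle and Cyp2a4 between the compounds were lost (adjusted p = 0.0963 and 0.11). With 3 libraries per group at these depths, 1.5-fold changes were recovered in 32.8% to 40.3% of simulated genes.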

Other observations

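The families and genes of this part and the test of direct STAT5 targets were chosen after the values were seen, while the test of sex-biased genes was set beforehand; camera with Benjamini-Hochberg adjustment over 16 families was used. In AdipoRonPEG5 livers, 9 of 18 genes of glutathione synthesis and peroxide removal rose and 0 fell against vehicle (median 0.33, adjusted p = 1.19e-06; adjusted p = 0.0309 with an estimated correlation). They include the peroxiredoxin Prdx1 (0.79 ± 0.080), the peroxidase Gpx4 (0.62 ± 0.085) and G6pdx, an enzyme that supplies NADPH (0.82 ± 0.15). Against AdipoRon, 5 rose (median 0.30, adjusted p = 7.28e-12; adjusted p = 0.00648 with an estimated correlation). The macrophage list had medians of 1.84 and 0.35 in these comparisons, and a macrophage part was not tested. With AdipoRon against vehicle 1 rose and 1 fell (median -0.039, adjusted p = 0.606). The peroxidase Gpx2 had 136 counts over the AdipoRonPEG5 libraries against 1 over the vehicle libraries, a ratio of 182 (95% interval 32.0 to 7223). Glutathione transferases as a family had 10 rises and 3 falls among 20 genes against vehicle (median 0.59, adjusted p = 7.51e-05; adjusted p = 0.306 with an estimated correlation), with Gstm4 at 2.86 ± 0.17, Gsta4 at 1.66 ± 0.21 and Gstk1 at -0.71 ± 0.11.

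Iron and haem genes moved in the same livers: 6 of 14 rose and 1 fell with AdipoRonPEG5 against vehicle (median 0.35, adjusted p = 0.00027; adjusted p = 0.156 with an estimated correlation), and 5 rose against AdipoRon (median 0.30, adjusted p = 8.63e-05; adjusted p = 0.273 with an estimated correlation). Macrophages express many of these genes. Their list had medians of 1.84 and 0.35 in these comparisons, and their part was not tested. The ferritin genes Fth1 (1.18 ± 0.12) and Ftl1 (0.82 ± 0.11) store iron, Blvrb (1.49 ± 0.10) reduces biliverdin, and Slc48a1 (1.21 ± 0.10) transports haem. Hamp2, a hepcidin gene, was at -2.78 ± 0.70, but the call ended without vehicle 1, vehicle 2, AdipoRonPEG5 1 or AdipoRonPEG5 3 (adjusted p from 0.0513 to 0.0858), and the value without vehicle 1 was -2.05. Guanylate-binding proteins are interferon-induced GTPases. With AdipoRonPEG5, 9 of 9 rose (median 1.85, adjusted p = 1.27e-06, or 0.156 with an estimated correlation). With AdipoRon, 7 of 9 rose (median 1.35, adjusted p = 2.65e-06, or 0.261 with an estimated correlation).

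Cish, Onecut1 and Bcl6 among the largest changes raised the hypothesis that both compounds may act as growth hormone does on direct targets of the transcription factor STAT5. Growth hormone raises Cish, Socs2 and Onecut1 and lowers Bcl6. Cish, Onecut1 and Bcl6 prompted the hypothesis, so that their calls are no evidence for it, and only Socs2 is a further gene. Socs2 passed with AdipoRonPEG5 and not with AdipoRon (1.52 ± 0.27 and 0.65 ± 0.28, edgeR Benjamini-Hochberg adjusted p = 0.00404 and 0.202). The count of direct STAT5 targets past the threshold, 3 of 4 with AdipoRon, is thus that of the prompting genes alone, and there the call of Onecut1 ended with only the 2 groups fitted (adjusted p = 0.0504) or without vehicle 1 (adjusted p = 0.0608). The growth hormone target list passed with neither compound (camera Benjamini-Hochberg adjusted p = 0.0859 and 0.948). Of 18 major urinary protein genes, which growth hormone also controls, 9 fell and 1 rose with AdipoRonPEG5 (median -1.44, adjusted p = 5.75e-05; adjusted p = 0.325 with an estimated correlation); with AdipoRon, 0 fell and 0 rose (median -0.085, adjusted p = 0.523; adjusted p = 0.95 with an estimated correlation). Cytokines other than growth hormone also act through STAT5, so that these genes leave the source open. A shift toward female-biased liver genes, as under continuous growth hormone, was tested on 9 female-biased and 18 male-biased genes. Their medians with AdipoRonPEG5 were -0.84 and -0.20 (difference -0.63, 95% interval -1.37 to 1.36; permutation p = 0.122, two-sided). A missed threshold had been set as evidence against a shift, but the interval spans both signs and the list left out the called gene Cyp2a4, so the test does not decide; with Cyp2a4 the difference was -0.30 (permutation p = 0.364). With AdipoRon the female-biased genes lay lower than the male-biased ones, opposite to such a shift (difference -0.81, 95% interval -1.14 to -0.44, permutation p = 0.00012, which treats genes as independent). There edgeR called 0 of 9 female-biased and 0 of 18 male-biased genes (1 and 0 at an unadjusted p under 0.05; 1 and 0 with DESeq2; 0 and 0 with limma-voom). The female-biased genes as a set did not pass (camera Benjamini-Hochberg adjusted p = 0.223; adjusted p = 0.77 with an estimated correlation).

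Acute phase genes set single libraries apart. Saa2 was at 3498 CPM in vehicle 3 and 1605 CPM in AdipoRonPEG5 1, against 15.7 to 213 CPM in the other 7 libraries.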
